A study of Mus musculus with 12 samples.

How the data were processed

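RNA was measured in isolated glomeruli of 12 female mice aged 8 to 10 weeks, in 4 groups of 3, C57BL6J control, C57BL6J anti-GBM GN, 129S2SvPAs control and 129S2SvPAs anti-GBM GN. Per the labels' protocols, biotin-labelled RNA was hybridised to Affymetrix arrays, 1 array per mouse. The deposited values are log2 probe set signals, rounded to 2 decimals, for 45037 probe sets on each array. Per the submitters' processing notes, MAS5 and GCRMA were used, with no version given and without saying which of them made the values. The log2 scale was read from the values, which run from 1.12 to 15.02, and no centring of genes was seen. The column medians, in replicate order, were 3.01, 3.00 and 3.01 for C57BL6J control, 3.02, 3.03 and 2.99 for C57BL6J anti-GBM GN, 3.03, 3.03 and 3.04 for 129S2SvPAs control and 3.05, 3.02 and 3.06 for 129S2SvPAs anti-GBM GN. Many values lie on a dense floor near these medians, so a difference from or to the floor understates the true one. Array and scan dates were not given in the sources used here, and no batch could be tested.

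Probe sets were named through the platform's annotation table. Of the 45037 probe sets 34957 had 1 gene symbol, 920 had several and 9160 had none, and those of the last 2 kinds were left out of the named comparisons. Symbols were looked up by Entrez identifier for 34741 probe sets in a RefSeq gene table, 155 more carried a current symbol and 61 kept the annotation's symbol. No symbol was changed by this. No coordinates are given because the values name no genome build. Each of the 18201 genes was represented by its probe set with the highest mean, and no probe's level was set against another probe's. Genes were tested when that probe set exceeded the median of the whole table, 3.03, on at least 3 arrays, which left 11921 genes.

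Differences were tested in R 4.3.3 with limma 3.58.1. One mean per group was fitted over all 12 arrays, which share 1 estimate of the spread, followed by contrasts and empirical Bayes moderation with 10.7 total degrees of freedom. The p-values were Benjamini-Hochberg adjusted within each contrast and a gene was called at an adjusted p under 0.05. The 6 contrasts were anti-GBM GN minus control in each strain, the average of these, their difference (129S2SvPAs minus C57BL6J), and 129S2SvPAs minus C57BL6J in controls and in anti-GBM GN. Gene lists with at least 5 tested members were tested with limma's camera, 2-sided, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, Benjamini-Hochberg adjusted over 168 tests (28 of 32 lists in 6 contrasts). With the preset correlation 85 of the 168 tests passed, and with an estimated correlation none passed in camera, although 30 had an unadjusted p under 0.05.

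The lists, the contrasts, the alternatives and the rule for named genes were fixed before the data were examined. Some tests of technical explanations in the closing section were added or changed after results were seen, as stated there. The rule takes, per contrast, the 5 largest rises and the 5 largest falls past the threshold whose arrays do not overlap between the groups (no such condition for the difference of responses), up to 4 members of each list with the lowest p, and 16 fixed genes. The set of circadian clock genes in the closing section was chosen after values were seen, and of its members only Dbp and Ciart are also named by this rule.

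The fits were tested on simulated data with each gene's real mean over all arrays and its real spread. In these, 200 of 11921 genes were changed singly and a list of 30 others was shifted. Noise was normal and independent between genes, with the same SD in all groups. Correlated genes and an array that stands apart were therefore not simulated, and error rates in the real data can differ. At a true log2 change of 1, limma recovered 63% in the C57BL6J response, 70% in the 129S2SvPAs response, 83% in the average, 36% in the difference of responses, 69% between controls and 70% between challenged mice, with at most 18 false calls among 11691 unchanged genes in any contrast and none with the wrong sign. At a change of 2 the shares were 94%, 97%, 99%, 73%, 94% and 98%.

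The alternatives were quantile normalization, a shift of each array to one median, no filter, a stricter filter at the 75th percentile, the mean of all probe sets of a gene, all probe sets counted singly, a trended and robust prior, array weights, a fit of only the groups compared, the replicate number as a block, the mean of the proximal tubule markers as a covariate, an absolute log2 change of at least 1, and leaving out each array. Labels of the arrays were also regrouped, with all 10 splits for contrasts of 3 against 3 and 100 draws within strains for the average. For the difference of responses, residuals of an additive fit of strain and treatment were exchanged among arrays in 100 draws, and again only among arrays with the same replicate number. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.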

Results

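The study measured transcripts in glomeruli, the filtering units of the kidney, from female mice of the inbred strains C57BL6J and 129S2SvPAs, with or without anti-GBM glomerulonephritis (anti-GBM GN). In this model, serum raised against the glomerular basement membrane is injected and antibody binds along the capillary wall. Serum was given on days 0, 1 and 2, and kidneys were taken on day 4. Glomeruli were isolated by passing tissue through sieves of 100 and 45 µm. Each of the 4 groups (control and anti-GBM GN in each strain) held 3 mice, with 1 Affymetrix mouse array per animal. The values were log2 probe set signals between 1.12 and 15.02, with array medians of 2.99 to 3.06, and 11921 genes were tested. The number of arrays limits the precision. Differences are given on the log2 scale with the standard error (SE) of limma's moderated test, and p-values are Benjamini-Hochberg adjusted.

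**Figure D1:**
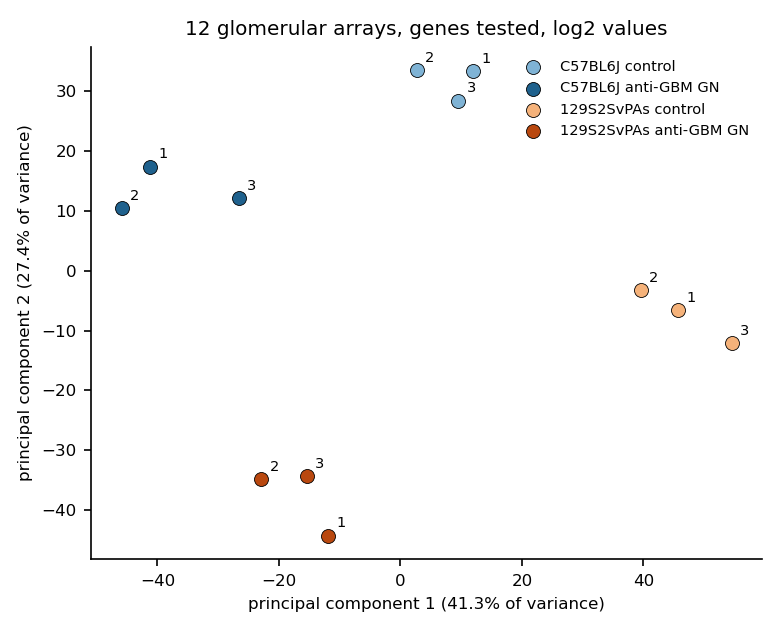
Positions of the 12 arrays on the first 2 principal components of the genes tested, in log2 units, with colour for the group and the number for the replicate. Each point is 1 array of glomeruli from 1 mouse.

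The first comparison asked what anti-GBM GN changed in C57BL6J glomeruli. Transgelin (Tagln), an actin-binding protein of smooth muscle, rose from 6.29 ± 0.47 to 11.59 ± 0.48 (SD, n = 3 in each group), a change of 5.29 (SE 0.27, adjusted p = 4.31e-06 in limma). Ch25h, the cholesterol 25-hydroxylase, rose by 5.40 (SE 0.25) and Igfbp2, which binds insulin-like growth factors, by 4.51 (SE 0.27). Ppbp and Pf4, chemokines stored in platelets, rose by 4.77 (SE 0.44) and 4.31 (SE 0.40). Among genes past the threshold, the largest falls were in Esm1, an endothelial proteoglycan (-2.60, SE 0.18), and Ciart, a repressor of the circadian clock (-2.60, SE 0.65). Next were Gm266 (-2.58, SE 0.23), Ddn, which encodes the podocyte protein dendrin (-2.50, SE 0.43), and F8, coagulation factor VIII (-2.29, SE 0.39). The clock output factor Dbp was lower still, at -3.69 (SE 1.0), but with adjusted p = 0.051 in limma.

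Cell cycle genes moved together in C57BL6J, where 24 of 37 rose, or 28 adjusted over the list alone. Mki67, the proliferation antigen Ki-67, rose by 3.49 (SE 0.52), the mitotic checkpoint kinase Bub1 by 1.80 (SE 0.12), the spindle genes Hmmr and Tpx2 by 1.98 (SE 0.15) and 1.34 (SE 0.14), and the cell cycle inhibitor Cdkn1a by 3.82 (SE 0.41). The list's shift against other genes had adjusted p = 6.64e-26 in limma's camera test, and adjusted p = 0.141 with an estimated correlation. Epithelial injury and repair genes rose in 16 of 26 (17 adjusted over the list alone; camera adjusted p = 1.53e-16, adjusted p = 0.108 with an estimated correlation). Among them Tubb6, a tubulin, rose by 3.81 (SE 0.27), the secreted lipocalin Lcn2 by 3.31 (SE 0.37), the TWEAK receptor Tnfrsf12a by 2.66 (SE 0.23) and vimentin (Vim) by 2.49 (SE 0.17). Cd44 and Cd9, which encode surface glycoproteins, rose by 1.26 (SE 0.32) and 1.27 (SE 0.32), whereas Havcr1, the tubular injury marker KIM-1, had a value of 1.59 (SE 0.76) and adjusted p = 0.266.

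Matrix and cytoskeleton genes were also among those that rose in C57BL6J. In the extracellular matrix list 11 of 26 rose (18 adjusted over the list alone), with camera adjusted p = 3.78e-15 and adjusted p = 0.108 with an estimated correlation. Laminin gamma 1 (Lamc1) rose by 2.09 (SE 0.17), the basement membrane collagen genes Col4a1 and Col4a2 by 2.28 (SE 0.26) and 2.10 (SE 0.27), and tenascin C (Tnc) by 2.06 (SE 0.25). Actin cytoskeleton genes rose in 15 of 24 (19 adjusted over the list alone; camera adjusted p = 3.17e-17, adjusted p = 0.108 with an estimated correlation), among them Actn1 by 2.31 (SE 0.17) and Flna by 2.25 (SE 0.18). Of the mesangium and vascular smooth muscle list 3 of 15 rose, Tagln, Acta2 and Des (3 adjusted over the list alone; camera adjusted p = 8.07e-05, adjusted p = 0.234 with an estimated correlation).

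Interferon response genes in C57BL6J rose in 8 of 31 (10 adjusted over the list alone; camera adjusted p = 7.04e-10, adjusted p = 0.261 with an estimated correlation), with Rsad2 at 2.24 (SE 0.21) and Irf7 at 1.41 (SE 0.27). Leukocyte adhesion molecules rose in 5 of 12 (8 adjusted over the list alone; camera adjusted p = 1.88e-08, adjusted p = 0.108 with an estimated correlation), among them Vcam1 by 2.81 (SE 0.19) and E-selectin (Sele) by 1.83 (SE 0.29). Of 16 chemokines and cytokines 4 rose (4 adjusted over the list alone), namely Cxcl10 by 2.75 (SE 0.32), Cxcl13 by 1.99 (SE 0.32), Cx3cl1 by 1.71 (SE 0.29) and Cxcl1 by 1.37 (SE 0.28), with camera adjusted p = 0.000582 and adjusted p = 0.261 with an estimated correlation. Ccl2, the monocyte chemoattractant, lay near the floor at 2.89 ± 0.04 and 3.05 ± 0.20 (SD, n = 3). The platelet list rose in 4 of 6 (5 adjusted over the list alone; camera adjusted p = 2.13e-07, adjusted p = 0.108 with an estimated correlation). Of the immediate early and heat shock genes 10 of 21 rose (12 adjusted over the list alone; camera adjusted p = 6.12e-09, adjusted p = 0.141 with an estimated correlation), including Nr4a1 by 2.26 (SE 0.24) and Fos by 1.87 (SE 0.26). Coagulation and fibrinolysis genes rose in 9 of 19 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 1.35e-06, adjusted p = 0.203 with an estimated correlation), including the fibrinogen chain Fga by 3.17 (SE 0.44).

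Podocyte markers in C57BL6J showed 3 rises and 1 fall among 31 (4 and 2 adjusted over the list alone; camera adjusted p = 0.726). Nestin (Nes) rose by 1.57 (SE 0.29), Kirrel by 1.07 (SE 0.21) and Myo1e by 1.01 (SE 0.20), and Thsd7a, a podocyte membrane protein, fell by 1.84 (SE 0.36). The slit diaphragm gene Nphs1 was at -0.51 (SE 0.45, adjusted p = 0.59) and the transcription factor Wt1 at -0.96 (SE 0.39, adjusted p = 0.186). Endothelial nitric oxide synthase Nos3 rose by 2.86 (SE 0.33), while the endothelial gene Ehd3 fell by 1.94 (SE 0.39), in an endothelial list with 2 rises and 1 fall among 21 (7 and 2 adjusted over the list alone; camera adjusted p = 0.00088, adjusted p = 0.543 with an estimated correlation). Proximal tubule markers, a measure of tubule fragments among the glomeruli, had 2 falls in 25 (2 adjusted over the list alone), a median of -0.14 and camera adjusted p = 0.0604.

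Across all genes tested in C57BL6J, 845 passed an adjusted p of 0.05 in limma, 570 higher and 275 lower. In each of the 845 the challenged arrays did not overlap the control arrays. Such separation was seen in 29.1% of all genes tested, against 10% by chance for 3 against 3. With the proximal tubule markers as a covariate 349 genes passed, and with array weights 2021, of which 1023 were higher and 998 lower. Without C57BL6J anti-GBM GN replicates 1 and 2 or C57BL6J control replicates 1 and 3, left out singly, 512, 407, 482 and 495 passed.

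The second comparison asked what anti-GBM GN changed in 129S2SvPAs glomeruli. Lcn2 rose by 6.52 (SE 0.37, adjusted p = 4.2e-06 in limma), from 3.54 ± 0.09 to 10.07 ± 0.64 (SD, n = 3). Tagln rose by 5.70 (SE 0.27), Crct1 by 5.67 (SE 0.27), Apold1, an early response gene of endothelium, by 5.41 (SE 0.30), and Pf4 by 4.86 (SE 0.40). The largest falls were in Hpd, an enzyme of tyrosine breakdown (-4.40, SE 0.37), the membrane serine protease Tmprss4 (-3.98, SE 0.18), the distal tubule protein parvalbumin (Pvalb, -3.76, SE 0.42), the clock output factor Dbp (-3.69, SE 1.0) and Ddn (-3.67, SE 0.43).

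**Figure D2:**
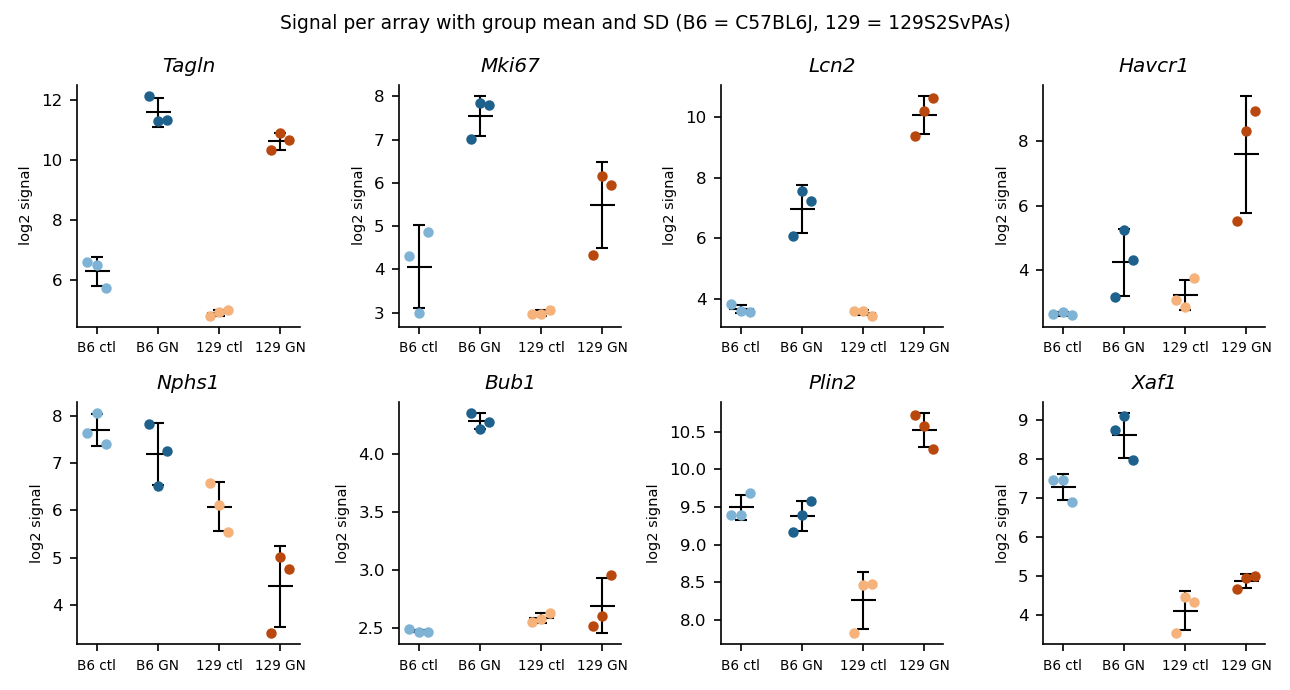
Log2 signal of 8 genes on each of the 12 arrays, by group (B6 stands for C57BL6J and ctl for control), with the group mean and SD (n = 3). Tagln and Lcn2 separated challenged from control arrays in both strains, and Xaf1 separated the strains.

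Injury genes rose in 20 of 26 in 129S2SvPAs (21 adjusted over the list alone; camera adjusted p = 6.97e-15, adjusted p = 0.108 with an estimated correlation). Havcr1 rose by 4.36 (SE 0.76), from 3.24 ± 0.46 to 7.60 ± 1.82 (SD, n = 3), Tnfrsf12a by 4.03 (SE 0.23), Vim by 3.12 (SE 0.17) and Cd44 by 2.53 (SE 0.32). Matrix genes rose in 17 of 26 (21 adjusted over the list alone; camera adjusted p = 5.49e-13, adjusted p = 0.108 with an estimated correlation), with the protease inhibitor Timp1 at 3.09 (SE 0.20), Lamc1 at 2.85 (SE 0.17) and Col4a2 at 2.84 (SE 0.27). Actin cytoskeleton genes rose in 17 of 24 (19 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.95e-12, adjusted p = 0.141 with an estimated correlation). Cell cycle genes rose in 17 of 37, or 22 without 129S2SvPAs anti-GBM GN replicate 1 (22 adjusted over the list alone; camera adjusted p = 1.47e-07, adjusted p = 0.341 with an estimated correlation), including Cdkn1a by 4.02 (SE 0.41), the replication helicase gene Mcm6 by 2.46 (SE 0.42) and Mki67 by 2.48 (SE 0.52).

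The endothelial list rose in 14 of 21 in 129S2SvPAs and fell in 1 (15 and 2 adjusted over the list alone; camera adjusted p = 7.53e-07, adjusted p = 0.391 with an estimated correlation). Nos3 rose by 3.73 (SE 0.33), the adhesion receptor Pecam1 by 2.67 (SE 0.38) and the roundabout receptor Robo4 by 2.45 (SE 0.26). The list's mean per array, relative to each gene's mean over all arrays, was low and scattered in the 129S2SvPAs controls. It was -1.001 ± 0.631 there and 0.237 ± 0.124 in anti-GBM GN (SD, n = 3). In C57BL6J it was 0.114 ± 0.303 in controls and 0.650 ± 0.341 in anti-GBM GN. The rise in 129S2SvPAs thus began from a lower level. Interferon response genes rose in 13 of 31 (14 adjusted over the list alone; camera adjusted p = 4.07e-06, adjusted p = 0.348 with an estimated correlation), with Rsad2 at 3.03 (SE 0.21) and the tetherin gene Bst2 at 1.18 (SE 0.18). Immediate early and heat shock genes rose in 13 of 21 (14 adjusted over the list alone; camera adjusted p = 2.79e-08, adjusted p = 0.144 with an estimated correlation). The leukocyte adhesion list rose in 6 of 12 (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00193, adjusted p = 0.261 with an estimated correlation). Of 16 chemokines and cytokines 6 passed in limma, and without 129S2SvPAs anti-GBM GN replicate 1 there were 5 rises and 1 fall. The neutrophil chemokine Cxcl1 rose by 3.76 (SE 0.28) and Il34 by 1.55 (SE 0.13), and the list as a whole had camera adjusted p = 0.131. Of 20 monocyte and macrophage markers 2 rose, Cd14 by 4.16 (SE 0.24) and Lgals3 by 1.37 (SE 0.24), with camera adjusted p = 0.851 for the list.

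Podocyte markers in 129S2SvPAs rose in 6 of 31 and fell in 4 (6 and 4 adjusted over the list alone; camera adjusted p = 0.634). Nphs1 fell by 1.68 (SE 0.45, adjusted p = 0.0218 in limma), the growth factor Vegfa by 1.42 (SE 0.32) and the cell cycle inhibitor Cdkn1c by 1.35 (SE 0.30), while Nes rose by 2.64 (SE 0.29) and podocalyxin (Podxl) by 1.18 (SE 0.23). Without 129S2SvPAs anti-GBM GN replicate 1 the list had 8 rises and 2 falls and a median of 0.06 instead of -0.05. Nphs1 was then at -1.19 (adjusted p = 0.0513). Tubule markers were lower in the challenged 129S2SvPAs arrays. Of the proximal tubule list 9 of 25 fell and 1 rose (15 and 1 adjusted over the list alone; median -0.67, camera adjusted p = 8.69e-06, adjusted p = 0.261 with an estimated correlation), and of the loop, distal tubule and collecting duct list 6 of 19 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0136, adjusted p = 0.542 with an estimated correlation). Cyp2e1 fell by 2.69 (SE 0.25), the calcium-binding gene Calb1 by 2.28 (SE 0.25) and Egf by 1.71 (SE 0.20). Oxidative phosphorylation genes fell in 5 of 24, or 2 without that array (5 adjusted over the list alone; median -0.34, camera adjusted p = 8.27e-05, adjusted p = 0.221 with an estimated correlation). In C57BL6J none of the 24 passed in limma, 9 had an unadjusted p under 0.05, and the list had camera adjusted p = 0.00036, with adjusted p = 0.261 with an estimated correlation.

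In all, 2424 genes passed in 129S2SvPAs, 1260 higher and 1164 lower, or 1107 and 1456 with the arrays shifted to one median. Replicate 1 of 129S2SvPAs anti-GBM GN stood apart from the other 2 of its group. Its Pearson's r to them was 0.974 and 0.973 across genes, which are not independent replicates, against 0.994 between them. Without it 2649 genes passed. With the proximal tubule markers as a covariate 12 genes passed, with array weights 3830, and in a fit of only the groups compared 1415. Under the covariate the log2 changes kept a slope of 0.943 on the original ones while their median SE grew by 2.50 times.

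**Figure D3:**
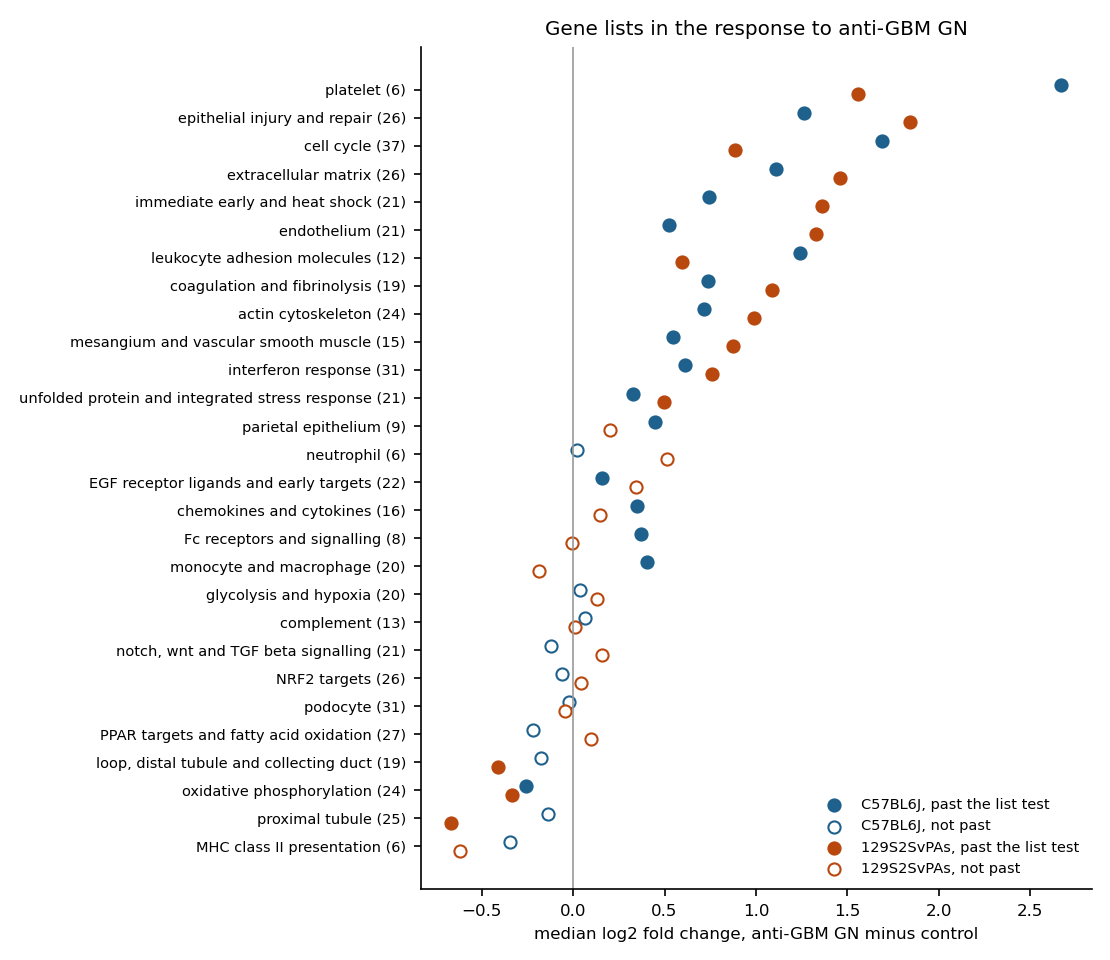
Median log2 change of each gene list from control to anti-GBM GN, for C57BL6J and 129S2SvPAs, with the number of genes tested in brackets. Filled points passed the camera test with the preset correlation and open points did not. None passed with an estimated correlation.

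Averaged over both strains, 3170 genes passed in limma, 1551 higher and 1619 lower, and the changes of the strains had Pearson's r = 0.75 and Spearman's rho = 0.664 across genes, which are not independent replicates. Of the genes called in each strain, 427 rose in both, against 60.2 for independent lists, and 180 fell in both, against 26.9. The number called with opposite signs in limma was 0, against 55.7 and 29.1 for independent lists. Both contrasts share 1 estimate of each gene's spread, so the lists are not independent and these numbers are only a reference. At an unadjusted p under 0.05 in both strains 18 had opposite signs. At Tagln the average was 5.50 (SE 0.19), at Ch25h 4.86 (SE 0.18) and at Apold1 4.50 (SE 0.21). Dbp fell by 3.69 (SE 0.71), Hpd by 3.23 (SE 0.26), Ddn by 3.08 (SE 0.31) and Slc8a1, the sodium-calcium exchanger, by 2.58 (SE 0.29). Cell cycle genes rose in 31 of 37 on average (32 adjusted over the list alone; camera adjusted p = 1.2e-16, adjusted p = 0.203 with an estimated correlation) and matrix genes in 22 of 26 (24 adjusted over the list alone; camera adjusted p = 1.64e-14, adjusted p = 0.108 with an estimated correlation). The fatty acid carriers Fabp4 and Fabp5 rose by 2.82 (SE 0.20) and 1.22 (SE 0.11), while the list of PPAR targets and fatty acid oxidation had 6 rises and 6 falls among 27 (6 and 6 adjusted over the list alone; camera adjusted p = 0.953). Pparg itself was at 0.10 (SE 0.12, adjusted p = 0.591). With the proximal tubule markers as a covariate 118 genes passed.

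**Figure D4:**
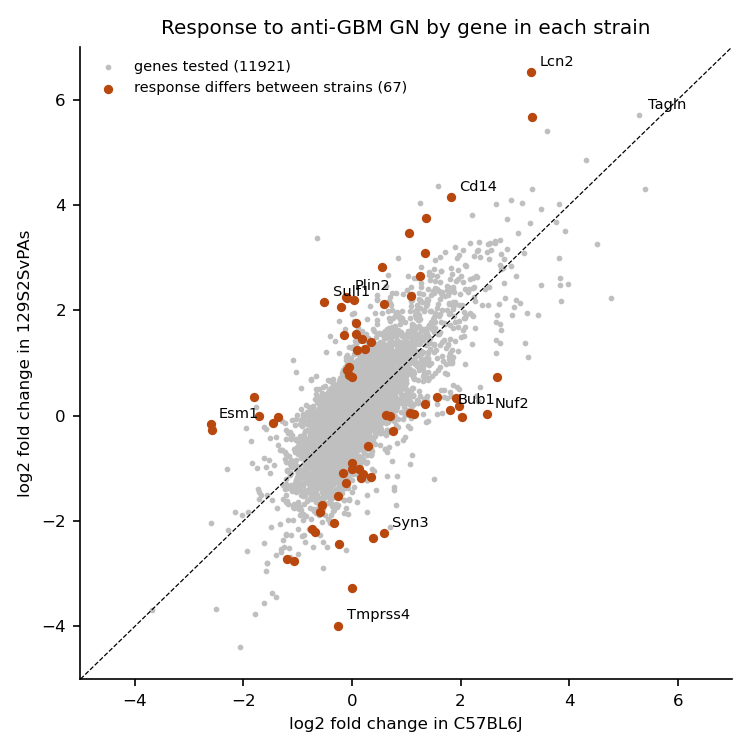
Log2 change from control to anti-GBM GN of each of the 11921 genes in C57BL6J (horizontal) and 129S2SvPAs (vertical), with the 67 genes whose change differed between strains in orange. The dashed line marks equal change.

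The series title asks how genetic background shapes the disease, and the difference of the 2 responses tests this gene by gene. Lcn2 rose by 3.22 more in 129S2SvPAs (SE 0.52, adjusted p = 0.0307 in limma), Cxcl1 by 2.38 more (SE 0.40), the fibrillar collagen gene Col5a3 by 2.42 more (SE 0.37), Timp1 by 1.75 more (SE 0.28) and Cd14 by 2.34 more (SE 0.34). Lcn2 belongs to both the injury and the neutrophil list. Of the 6 neutrophil genes tested 1 passed in limma and 3 had an unadjusted p under 0.05. For Sulf1, a heparan sulfate sulfatase, the difference was 2.66 (SE 0.38), since its level went from 3.43 ± 0.25 to 5.58 ± 0.30 in 129S2SvPAs and from 5.84 ± 0.29 to 5.33 ± 0.54 in C57BL6J (SD, n = 3). Esm1 differed by 2.44 (SE 0.26), with the fall in C57BL6J and levels of 5.52 ± 0.26 and 5.36 ± 0.17 in 129S2SvPAs (SD, n = 3). The lipid droplet gene Plin2 differed by 2.37 (SE 0.28) and the NRF2 targets Cbr3 and Txnrd1 by 2.26 (SE 0.32) and 1.27 (SE 0.19).

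Responses that were more negative in 129S2SvPAs included Tmprss4 (-3.73, SE 0.26) and Gm16316 (-3.27, SE 0.27). Others were the synaptic genes Syn3 (-2.82, SE 0.34) and Snap91 (-2.71, SE 0.46), and the kinetochore gene Nuf2 (-2.45, SE 0.22). Tmprss4 was already higher in 129S2SvPAs controls, as given below, so its fall in that strain began from a higher level. Nuf2 went from 2.82 ± 0.05 to 5.30 ± 0.38 in C57BL6J and lay near the floor in 129S2SvPAs, at 2.87 ± 0.02 and 2.90 ± 0.03 (SD, n = 3). Sequence variants of 129S2SvPAs under the probes, which could lower the signal in that strain, were not tested for any difference of responses. The cell cycle list had 4 genes with a smaller rise in 129S2SvPAs among 37 (8 smaller and 1 larger adjusted over the list alone; median -0.60, camera adjusted p = 4.04e-07, adjusted p = 0.347 with an estimated correlation), namely Bub1, Hmmr, Kif23 and Tpx2. Without 129S2SvPAs anti-GBM GN replicate 1 the median was -0.30, with these 4 and Anln smaller and Mcm6 larger. Mki67 differed by -1.01 (SE 0.74, adjusted p = 0.711) and Havcr1 by 2.77 (SE 1.08, adjusted p = 0.376, or 0.0291 without that array). Proximal tubule markers had a median difference of -0.44 (camera adjusted p = 3.14e-05, adjusted p = 0.286 with an estimated correlation) and endothelial markers 0.66 (camera adjusted p = 8.27e-05, adjusted p = 0.478 with an estimated correlation). Neither list had a gene past the threshold in limma, with 6 and 5 genes at an unadjusted p under 0.05. Endothelial markers were low and scattered in the 129S2SvPAs controls, as given above.

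Of all genes tested, 67 differed in response, 32 with a higher and 35 with a lower value in 129S2SvPAs, or 24 and 42 with the arrays shifted to one median. This count moved with each array left out, from 15 without 129S2SvPAs control replicate 2 to 136 without 129S2SvPAs anti-GBM GN replicate 1. It was 3 with the proximal tubule covariate, 286 with array weights, 18 with the stricter filter and 33 (21 higher, 12 lower) with the replicate number as a block.

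Between the strains' control glomeruli, Ugt2b38, a glucuronosyltransferase, was at 11.78 ± 0.28 in C57BL6J and 2.51 ± 0.05 in 129S2SvPAs (SD, n = 3), a difference of -9.26 (SE 0.15, adjusted p = 4.9e-11 in limma). Lower in 129S2SvPAs were also the lysosomal enzyme Galc (-6.47, SE 0.24), the steroid dehydrogenase Akr1c21 (-5.45, SE 0.44), Trim34a (-4.37, SE 0.18) and the methyltransferase Inmt (-4.35, SE 0.31). Akr1c21 belongs to the proximal tubule list. Each strain difference, here and in challenged mice, rests on a single probe set, and sequence variants of 129S2SvPAs under the probes were not tested for these genes. Higher were Gdpd3 (6.65, SE 0.22), the ribonucleases Rnase4 (5.42, SE 0.28) and Ang (4.35, SE 0.33), Abhd1 (5.07, SE 0.14) and Tmprss4 (4.21, SE 0.18). Nnt, the mitochondrial transhydrogenase that carries a deletion in C57BL6J, was higher by 1.27 (SE 0.18, adjusted p = 0.0013 in limma), and for Casp4, an inflammatory caspase, the difference was -1.49 (SE 0.23). Ren1 was not analysed here.

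Interferon response genes were lower in 129S2SvPAs controls in 21 of 31 (24 adjusted over the list alone; median -1.46, camera adjusted p = 2.55e-17, adjusted p = 0.144 with an estimated correlation). They included Xaf1 (-3.16, SE 0.31), the GTPase Iigp1 (-3.02, SE 0.34), Rsad2 (-2.71, SE 0.21) and Bst2 (-1.93, SE 0.18). Xaf1, however, was at 0.46 with the mean of all its probe sets (adjusted p = 0.349). Podocyte markers were lower in 14 of 31 (17 adjusted over the list alone; camera adjusted p = 1.78e-09, adjusted p = 0.302 with an estimated correlation), among them Wt1 (-1.93, SE 0.39), Sema3g (-1.83, SE 0.21), Kirrel (-1.72, SE 0.21) and Nphs1 (-1.62, SE 0.45). Endothelial markers were lower in 6 of 21 (18 adjusted over the list alone; camera adjusted p = 2.42e-09, adjusted p = 0.321 with an estimated correlation), such as Gpihbp1 (-1.97, SE 0.32) and Robo4 (-1.56, SE 0.26). Matrix genes were lower in 6 of 26 (8 adjusted over the list alone; camera adjusted p = 8.27e-05, adjusted p = 0.284 with an estimated correlation). Distal tubule markers were higher in 2 of 19 (2 adjusted over the list alone; camera adjusted p = 0.00899, adjusted p = 0.512 with an estimated correlation), and proximal tubule markers had camera adjusted p = 0.765.

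Between control glomeruli 1005 genes passed in limma, 396 higher and 609 lower in 129S2SvPAs, and with the arrays shifted to one median the split became 649 and 498. That shift moved the median difference of all genes to 0.103. The count was 503 without C57BL6J control replicate 2, 649 with the proximal tubule covariate and 1601 with array weights.

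In mice with anti-GBM GN, the largest strain differences involved many of the genes seen in controls. Ugt2b38 differed by -9.08 (SE 0.15, adjusted p = 6.09e-11 in limma), Akr1c21 by -6.44 (SE 0.44), Inmt by -6.23 (SE 0.31), Galc by -6.07 (SE 0.24) and the cytochrome Cyp2c23 by -4.80 (SE 0.28). Gdpd3 (5.93, SE 0.22), Rnase4 (4.84, SE 0.28), Abhd1 (4.55, SE 0.14), Angptl7 (3.66, SE 0.95) and Adat2 (3.48, SE 0.27) were higher in 129S2SvPAs. Of the genes called in each comparison, 154 were higher in 129S2SvPAs in both, against 13.8 for independent lists, and 266 were lower in both, against 29.8. Opposite strain differences were called for 5 genes higher in controls and lower in anti-GBM GN and for 1 the other way, against 19.4 and 21.3. Here too the shared estimate of the spread makes the numbers for independent lists only a reference.

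Between the challenged strains, Lcn2 was higher in 129S2SvPAs by 3.11 (SE 0.37) and Havcr1 by 3.36 (SE 0.76), and the injury list had 5 higher and 1 lower among 26 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00239, adjusted p = 0.329 with an estimated correlation). Lcn2 is also a member of the neutrophil list. Cdkn1c (-2.86, SE 0.30), Nphs1 (-2.79, SE 0.45) and Kirrel (-1.93, SE 0.21) were lower, within a podocyte list with 10 of 31 lower, or 6 without 129S2SvPAs anti-GBM GN replicate 1 (15 adjusted over the list alone; camera adjusted p = 9.7e-09, adjusted p = 0.306 with an estimated correlation). Cell cycle genes were lower in 13 of 37, or 11 without that array (19 adjusted over the list alone; camera adjusted p = 4.69e-09, adjusted p = 0.306 with an estimated correlation), with Kif23 at -2.15 (SE 0.24), Mki67 at -2.07 (SE 0.52) and Bub1 at -1.58 (SE 0.12). Mki67 was at -1.50 without the array (adjusted p = 0.0699) and at 0.16 with the proximal tubule covariate (adjusted p = 0.993). The interferon list was lower in 19 of 31 (25 adjusted over the list alone; camera adjusted p = 2.94e-18, adjusted p = 0.141 with an estimated correlation), led by Xaf1 (-3.74, SE 0.31). Xaf1 was at 0.72 with the mean of all its probe sets (adjusted p = 0.137).

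In challenged 129S2SvPAs glomeruli 7 of 20 monocyte and macrophage markers were lower and 1 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.000252, adjusted p = 0.426 with an estimated correlation). The lysosomal protease Ctss (-2.60, SE 0.52), the Fc receptor chain Fcer1g (-2.43, SE 0.50) and Ptprc, the leukocyte antigen CD45 (-1.97, SE 0.35), were lower, while Cd14 was higher (2.21, SE 0.24). The list's mean per array, relative to each gene's mean over all arrays, went from 0.133 ± 0.486 in C57BL6J controls to 0.630 ± 0.432 in anti-GBM GN. In 129S2SvPAs it went from -0.355 ± 0.573 to -0.409 ± 0.149 (SD, n = 3). In the C57BL6J response 2 of the 20 markers passed in limma. Of 16 chemokines and cytokines 3 were lower and 2 higher (6 and 2 adjusted over the list alone; camera adjusted p = 0.0929), with the B cell chemokine Cxcl13 (-3.44, SE 0.32) and Ccl5 (-2.58, SE 0.36) among the lower. Of the 27 genes of PPAR targets and fatty acid oxidation, 9 were higher and 1 lower, or 9 and 3 without 129S2SvPAs anti-GBM GN replicate 1 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0281, adjusted p = 0.24 without that array and adjusted p = 0.427 with an estimated correlation), including the enzymes Acot1 (2.10, SE 0.26) and Eci1 (1.44, SE 0.16). Proximal tubule markers were lower in 4 of 25 (5 adjusted over the list alone; camera adjusted p = 0.000734, adjusted p = 0.341 with an estimated correlation). In all, 999 genes passed in limma, 416 higher and 583 lower. Without C57BL6J anti-GBM GN replicate 1 or replicate 2 the count was 612 or 620, in a fit of only the groups compared 578, with the proximal tubule covariate 67 and with array weights 2256.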

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

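The tests without 1 array for the cell cycle list and the exchange within replicate numbers were chosen after the result was seen, as was the criterion that a value must also lie apart from the uncorrected one to count for an explanation.

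The response to anti-GBM GN differed between strains for 67 genes in limma. With the residuals of a fit without that difference exchanged among the 12 arrays, 2 of 100 groupings gave as many, the real one included, and the highest other called 107. With the exchange kept within replicate numbers 2 of 100 did and the highest other called 89. With a replicate block as well, 33 genes were called, 2 of 100 gave as many and the highest other called 195. Chance can be excluded at a share of 0.05 only for the count, and only if residuals can be exchanged between arrays. That is uncertain, since 129S2SvPAs anti-GBM GN replicate 1 stood apart. Single genes were less stable, and without 129S2SvPAs control replicate 2 only 14 of the 67 were still called. Genes with a more positive response in 129S2SvPAs were Lcn2 (3.22), Sulf1 (2.66), Esm1 (2.44), Col5a3 (2.42), Cxcl1 (2.38), Plin2 (2.37), Cd14 (2.34), Cbr3 (2.26), Timp1 (1.75) and Txnrd1 (1.27), on the log2 scale. Genes with a more negative response were Tmprss4 (-3.73), Gm16316 (-3.27), Syn3 (-2.82), Snap91 (-2.71), Nuf2 (-2.45), Kif23 (-2.05), Hmmr (-1.79), Bub1 (-1.69) and Tpx2 (-1.12). Of these, Tmprss4 began from a higher level in 129S2SvPAs controls than in C57BL6J controls. Sequence variants of 129S2SvPAs under the probes were not tested for the genes of either direction.

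The same test applied to gene lists picked out 10 of 28 by camera with the preset correlation and none with an estimated one, where the smallest adjusted p was 0.261 and 0 of the 28 had an unadjusted p under 0.05. The median differences were 0.66 for endothelium, -0.44 for proximal tubule, -0.327 for loop, distal tubule and collecting duct, -0.553 for monocyte and macrophage, -0.597 for cell cycle, 0.242 for extracellular matrix, -0.332 for Fc receptors and signalling, 0.268 for NRF2 targets, 0.552 for epithelial injury and repair and 0.297 for immediate early and heat shock genes. Without 129S2SvPAs anti-GBM GN replicate 1 the Fc receptor list was at -0.274 (camera adjusted p = 0.0742) and the extracellular matrix list at 0.375.

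Probe sets outside the named comparisons also carried signal. Of 2456 tested probe sets with no gene symbol 78 passed in limma in C57BL6J and 201 in 129S2SvPAs, and of 617 with several symbols 32 and 96.

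Over the cell cycle list the median difference of response was -0.60 (SE 0.36 over arrays), within 2 SE of 0. Here and below, an SE beside a list's median is that of the list's mean over arrays. The median of -0.60 rests partly on 129S2SvPAs anti-GBM GN replicate 1. Its mean cell cycle score was -0.398 against 0.649 and 0.535 in the other 2 arrays of its group. Without that array the median was -0.30 (SE 0.16), yet 5 genes were smaller and 1 larger in limma (camera adjusted p = 0.00177, adjusted p = 0.399 with an estimated correlation), among them all 4 called with every array, which argues against that array as the cause for these 4. In the 20 brighter genes of the list by mean over all arrays, where the floor matters less, the median was -0.28 (SE 0.45). In the 17 dimmer genes it was -1.12 (SE 0.25). The split uses the challenged arrays too, so a gene that rose less in 129S2SvPAs tends to fall in the dimmer part. The medians of -0.30 and -0.28 lie within 2 SE of 0, as the criterion first written for a single array or for compression at the floor required. The median of -0.60 with all arrays and genes already did so, and meeting that criterion therefore decides nothing. Both also lie within 2 SE of -0.60. For the list's median a single array, compression of dim probe sets and a weaker proliferative response of this strain therefore cannot be told apart, because the errors are too wide. Sequence variants of 129S2SvPAs under the probes were not tested for this list and stay open too, also for the 4 genes called with every array.

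For the other counts the regrouping said the following. The average response called 3170 genes, 1 of 100 splits gave as many and the highest other gave 930. Chance can be excluded at a share of 0.05 for this count, but only if arrays can be exchanged within a strain. That is uncertain here too because of 129S2SvPAs anti-GBM GN replicate 1. The contrasts of 3 against 3 have only 10 splits, too few for a share under 0.05, and in each only 1 of the 10, the real one, gave as many genes. The real split and the highest other called 845 and 1 genes in C57BL6J, 2424 and 2 in 129S2SvPAs, 1005 and 0 between controls, and 999 and 2 between challenged mice.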

How the results depend on the processing

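The number of arrays limits the precision, and the floor limits what dim probe sets can show. Of the 204 gene results printed in the text 184 passed in limma, 81 of them under every alternative that gave a value for them. Of the 184, 3 changed direction under some alternative. Of 64 list results 50 passed in camera, and with an estimated correlation 0 passed. A log2 step with 16 added was not run, because the values were on that scale already.

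An absolute log2 change of at least 1, which by construction removes smaller changes, left 468 genes in C57BL6J, 1109 in 129S2SvPAs, 744 on average, 570 between controls and 554 between challenged mice. Counting all probe sets singly, which by construction counts some genes repeatedly, gave 3737 in 129S2SvPAs, 4960 on average, 1706 between controls and 1589 between challenged mice. For the following the cause was not tested. Array weights gave 2021 in C57BL6J, 3830 in 129S2SvPAs, 286 for the difference of responses, 1601 between controls and 2256 between challenged mice. A fit of only the groups compared gave 1415 in 129S2SvPAs and 578 between challenged mice, and the stricter filter 18 for the difference of responses. The estimated correlation left 0 of the 85 list tests. Leaving out 1 array gave 407 to 1141 in C57BL6J, 1768 to 2649 in 129S2SvPAs, 2429 to 3500 on average, 15 to 136 for the difference, 503 to 1288 between controls, 612 to 1117 between challenged mice and 78 to 93 list tests.

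The proximal tubule covariate left 349 genes in C57BL6J, 12 in 129S2SvPAs, 118 on average, 3 for the difference, 649 between controls and 67 between challenged mice. Calls ended through wider errors, with median SE ratios of 1.34, 2.50, 2.45, 1.43, 1.18 and 2.26 and slopes of the log2 changes from 0.943 to 1.01. Direction changed under it for Mki67 between challenged mice (0.16) and for the proximal tubule list, from which the covariate is built, in 129S2SvPAs (0.272) and between challenged mice (0.275). With the mean of all probe sets Xaf1 changed direction, to 0.46 between controls and 0.72 between challenged mice, and the cause was not tested.

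The groups share replicate numbers, which the labels do not tie to a common litter or day. Same-number arrays had residual correlations of -0.38 to 0.33, over 0.1 in 11 of 18 pairs, including all 3 between C57BL6J anti-GBM GN and control (0.208 to 0.33) and all 3 between the controls of the strains (0.239 to 0.284), and 3 of the 12 arrays correlated best with their own number in every other group, a hint from the data and not from the design. With a replicate block the difference of responses called 33 genes (21 higher, 12 lower) instead of 67, 30 of them shared, and the other counts stayed within 1.5 times.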

Other observations

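All tests of clock genes concern a set chosen after its change was seen, and the subtraction of the tubule markers was added after the covariate's result was seen. An SE beside the median of a set of genes is that of the set's mean over arrays.

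In C57BL6J the Wnt ligand gene Wnt4 rose by 2.20 (SE 0.32), the Wnt feedback gene Nkd1 by 1.77 (SE 0.27) and Tgfb2 by 1.80 (SE 0.18), and the Notch target Hey1 fell by 1.95 (SE 0.27), with 3 rises and 4 falls among 21 genes of notch, wnt and TGF beta signalling (3 and 5 adjusted over the list alone; camera adjusted p = 0.88). In 129S2SvPAs Wnt4 rose by 1.37 (SE 0.32) and Tgfb2 by 1.01 (SE 0.18), with 4 rises and 1 fall (4 and 2 adjusted over the list alone; camera adjusted p = 0.218). Complement genes had 0 calls among 13 in C57BL6J in limma and 2 at an unadjusted p under 0.05, and in 129S2SvPAs Serping1 rose by 1.12 (SE 0.20) while Cfb fell by 0.77 (SE 0.14) and C1ra by 0.77 (SE 0.16). Glycolysis and hypoxia genes rose in 5 and fell in 1 of 20 in C57BL6J (7 and 2 adjusted over the list alone; camera adjusted p = 0.125), including Pfkp by 1.1 (SE 0.16) and Adm by 1.98 (SE 0.36). NRF2 targets rose in 5 and fell in 2 of 26 in 129S2SvPAs (6 and 3 adjusted over the list alone; camera adjusted p = 0.256), among them Hmox1 by 4.03 (SE 0.39).

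Of 10 clock output genes 7 fell in anti-GBM GN on average over the strains in limma, against 2 in C57BL6J and 5 in 129S2SvPAs, where Per1 (0.14) and Nr1d1 (0.08) were not lower, and the average had a median of -1.40 (SE 0.37 over arrays). The 7 were Dbp (-3.69), Ciart (-2.32), Per3 (-2.22), Per2 (-1.56), Tef (-1.53), Hlf (-1.27) and Nr1d2 (-1.12), with Per2 at adjusted p = 0.0505 without 129S2SvPAs anti-GBM GN replicate 1. Genes of the opposite phase had a median of 0.99 (SE 0.33) over 5 genes, of which Arntl (2.21) and Nfil3 (1.65) rose. Fewer tubule fragments in challenged preparations were set against this in 2 ways: with the proximal tubule markers as a covariate the median was -0.92 (SE 0.94), within 2 SE of 0 as that explanation required but too wide to decide, and with the median change of 31 tubule markers (-0.45, SE 0.11) taken off it was -1.0 (SE 0.36), which argues against it as the whole cause. The pair of opposite shifts is consistent with challenged and control mice being killed at another time of day, and equally with a clock shifted by the disease, which was not tested, since the labels give no time of killing.

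Interferon response genes were lower in 129S2SvPAs controls, with a median of -1.46 (SE 0.20 over arrays) over 31 genes. With the mean of the podocyte and endothelial markers as a covariate the median was -0.91 (SE 0.41), which argues against a lower share of glomeruli as the whole cause. Sequence variants of 129S2SvPAs under the probes could lower the signal without a change in transcript. The 13 other probe sets of these genes had a median of -0.38 and a mean of -0.71 (SE 0.15 of the mean), with 61.5% lower. The median and the share fell short of the bound of -0.5 and 80% set beforehand for ruling this out, although the mean lay past -0.5. Variants, a lower share of glomeruli and a lower basal interferon tone of the strain therefore cannot be told apart here, and the last was not tested.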
